A study of Phaeodactylum tricornutum with 18 samples.

How the data were processed

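RNA was sequenced from cultures of Phaeodactylum tricornutum strain Pt-1, a marine diatom, kept in medium with or without atrazine and sampled at 12 h, 2 d and 7 d. Per the labels' protocols, total RNA was extracted from cell pellets with Trizol and libraries followed standard Illumina protocols. The 18 libraries form 6 groups of 3 replicates, and group and replicate were taken from the sample labels. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical in part. The atrazine concentration is not given in the sources used here.

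The deposited table holds FPKM values, which scale fragments by gene length and by the mapped total of the library, for 10618 gene IDs in the 18 libraries, as its values and layout show. FastQC and TopHat2 version 2.0.8 are named per the submitters' processing notes. The counting tool, genome build and annotation are not given in the sources used here. Of the IDs, 10395 are numbered with the prefix gene and 223 carry another prefix. The table does not pair its IDs with gene names, and 0 of them matched the reference gene table. Lengths recovered from the FPKM steps followed the row order of that table by the number in the ID (r = 0.978 on the log scale over 10154 IDs, and 0.039 with the rows moved by 1), but an ID's place in that order was not taken as its name, and the match was not used. Stray carriage returns in 1 row were stripped on reading. All 18 value columns matched a sample title.

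Because genes carry no names, the 24 gene lists fixed before the data were examined (photosynthesis, light harvesting, carbon and nitrogen metabolism and others) were not filled, and no list test was run. The rule for named genes then allowed, for each atrazine comparison, at most 2 IDs that rose and 2 that fell. They are those with the largest log2 fold changes among IDs with an adjusted p under 0.05 and all 3 treated libraries on the same side of all 3 controls. For the same reason reads shared between paralogs or overlapping genes were not examined.

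FPKM carries no read totals, but the values of a gene across libraries were whole multiples of a common step once each library had its own depth factor, within a tolerance of 0.02. From these steps whole reads were recovered for 10355 of the 10460 genes above 0 (99.0%). The recovered totals ran from 18496658 to 19526198 reads per library, a ratio of 1.06. At the median recovered gene length of 1283 bp, an FPKM of 1 stood for 24.3 reads. On simulated reads for 10355 genes the step was found for 99.9%, and all reads were right for 100% of those.

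Tests were run in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1). Genes entered with a mean FPKM of at least 1 over the 18 libraries, which left 9972. All 18 libraries were fitted together with a mean per group, moderated variances with an intensity trend and no block. Contrasts were atrazine minus control at each time, the differences of these effects between times, and the control groups between times. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Summaries and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

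FPKM is relative to each library's total, so a shift of a few abundant transcripts moves all others. Each comparison is therefore also given after rescaling each library by the median ratio of its values to the geometric mean over libraries. The 12-h fit was tested on simulated data of 9972 genes: it recovered 10.6% of 66 genes changed by 0.5 on the log2 scale, 62.7% of 67 changed by 1 and 100% of 67 changed by 2, and called 0.10% of 9772 unchanged genes. For 2 d these shares were 13.6%, 68.7%, 97.0% and 0.06%, and for 7 d 19.7%, 71.6%, 100% and 0.06%. The simulation changed only these few genes per comparison and left 9772 unchanged. The real tests called 65.8% of genes at 12 h, 30.0% at 2 d and 75.4% at 7 d. With few changed genes the adjusted p threshold is stricter on the raw p, so the simulated shares do not describe the real tests.

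Alternatives written before the data were examined were a pseudocount of 0.1, no expression filter, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, a replicate block, no intensity trend, an absolute log2 fold change of at least 1, only the 6 libraries of a time, and leaving out each replicate. Chosen after seeing the data were voom on the recovered reads, removal of the 100 most abundant genes, rescaling with each library of 12 h or 7 d left out, and leaving out replicates for the correlations between times. Single values per library were compared with two-sided exact permutation tests. With 3 libraries against 3 an exact permutation test cannot go below p = 0.1. The chi-square per gene between the reads of replicate libraries ran from 4.77 to 156, far above the value of 1 that counting noise gives, so no library was taken for a copy of another.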

Results

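The transcriptome of Phaeodactylum tricornutum Pt-1 was measured by RNA sequencing in cultures with and without atrazine, a triazine herbicide that blocks electron transport at photosystem II. The study title names photosynthetic physiology and central carbon metabolism as its subject, at an environmental dose. Cultures were sampled at 12 h, 2 d and 7 d, with 3 control and 3 atrazine libraries at each time. Recovered depth was even, between 18496658 and 19526198 reads per library. The table listed 10618 IDs, of which 9972 had a mean FPKM of at least 1 and were tested. It does not pair IDs with gene names, so photosynthesis and carbon metabolism genes were not followed as groups, and genes are given by ID. No position or product is given for them.

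Libraries grouped by time and by treatment. Sampling time separated the control groups along the first principal component of log2(FPKM + 1), which held 58.1% of the variance, and the second held 15.9%. Within groups, pairs of libraries correlated across genes at 0.966 to 0.996. Between control and atrazine libraries the correlation was 0.881 to 0.906 at 12 h, 0.954 to 0.967 at 2 d and 0.834 to 0.919 at 7 d. Replicate 3 of the 12-h controls stood apart, at 0.966 and 0.969 with the other 12-h controls, which correlated at 0.990 with each other. Replicate 2 of the 12-h atrazine cultures did too, at 0.975 and 0.971 with the others, which correlated at 0.992. To a lesser degree so did replicate 3 of the 7-d atrazine cultures, at 0.981 with each of the others, which correlated at 0.996.

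**Figure D1:**
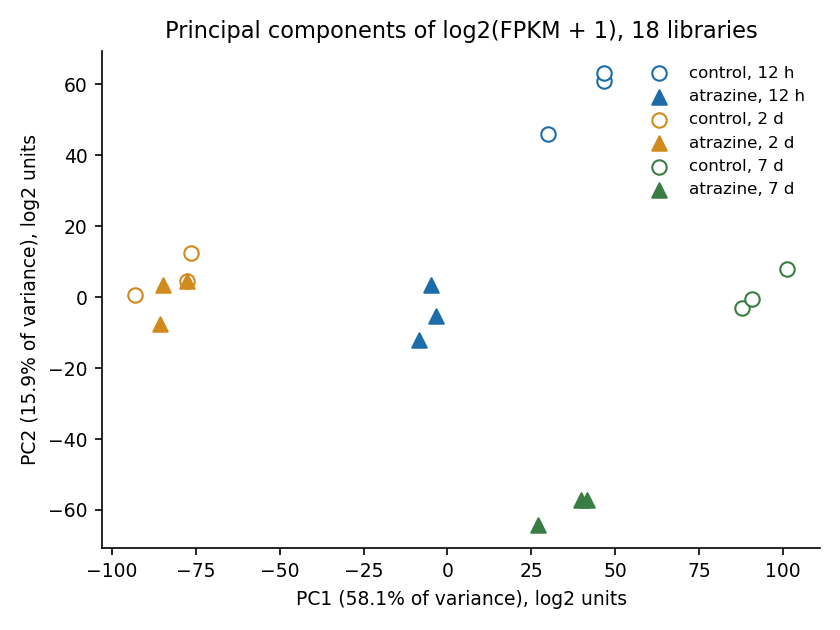
Each point is a library, placed by its first and second principal components of log2(FPKM + 1), which hold 58.1% and 15.9% of the variance. Open circles are controls, filled triangles are atrazine cultures, and colours mark the times; at 2 d the treatments lie close together, and at 12 h and 7 d they lie apart.

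By the number of genes that carried 50 percent of all FPKM, transcripts were concentrated in fewer genes in atrazine cultures. At 12 h, this number was 442 ± 66.8 (SD, n = 3) in controls and 237 ± 2.65 in atrazine cultures. At 2 d the numbers were 208 ± 6.56 and 159 ± 9.02, and at 7 d 686 ± 38.6 and 436 ± 1.00 (SD, n = 3). All 3 treated libraries lay below all 3 controls at each time, and an exact permutation test of 3 against 3 gave p = 0.1 each, the smallest it allows. Over the 3 times together, with labels permuted within time, the exact permutation p was 0.00025, the smallest of the 8000 arrangements, and 0.000625 after Benjamini-Hochberg adjustment over 5 library measures. The share of FPKM in the 10 most abundant genes of a library did not go the same way at each time. It was 7.71% ± 0.403 in controls and 11.5% ± 0.721 with atrazine at 12 h, 10.8% ± 0.659 and 14.4% ± 0.587 at 2 d, and 8.79% ± 0.0410 and 7.97% ± 0.641 at 7 d (SD, n = 3), where all 3 treated libraries lay below all 3 controls. The recovered depth did not pass the same test (permutation p = 0.198).

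Control libraries differed strongly between times, which sets the background for the herbicide comparisons. Each time has its own libraries, so culture age cannot be told apart from other differences between samplings. Between 12 h and 2 d, 1078 genes rose and 6910 fell, with a median log2 change of -0.93. Between 12 h and 7 d, 5601 rose and 1668 fell, with a median of 0.53 (limma, adjusted p under 0.05). After median-ratio rescaling the splits were near even, with 3350 higher and 3675 lower at 2 d, and 2494 higher and 2771 lower at 7 d. Rescaling centres the ratios of each library, so a near-even split is largely its product. The number of genes carrying 50 percent of FPKM in controls went from 442 at 12 h to 208 at 2 d and 686 at 7 d.

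At 12 h most genes were lower in atrazine cultures. The largest falls were in gene1093, from 1314 ± 92.9 to 20.4 ± 8.84 FPKM, and gene7272, from 544 ± 59.4 to 7.48 ± 1.29 FPKM (SD, n = 3). Their log2 fold changes were -6.02 (SE 0.22) and -6.01 (SE 0.18), with limma adjusted p of 9.87e-14 and 1.40e-14. The largest rises were in gene9921, from 7.55 ± 3.94 to 153 ± 72.5 FPKM, and gene2447, from 4.65 ± 2.87 to 58.7 ± 11.1 FPKM (SD, n = 3). Their log2 fold changes were 4.17 (SE 0.38) and 3.56 (SE 0.29), with limma adjusted p of 2.83e-08 and 5.90e-09. After rescaling these IDs changed by -5.46, -5.47, 4.68 and 4.04 on the log2 scale.

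Of the genes tested at 12 h, 1007 rose and 5555 fell (65.8% in all). The median log2 fold change over all genes was -0.51, and 77.1% of genes lay below 0. Relative to that shift, with libraries rescaled by median ratio, 2610 genes were higher and 2629 lower. Every one of the 1007 genes that rose as deposited also rose after rescaling, and 2629 of the 5555 that fell also fell. Rescaling raised the fold changes by a like amount across genes (lower quartile from -0.96 to -0.45, upper quartile from -0.06 to 0.46). The kept rises thus follow from the method and are no separate support. Of the 100 most abundant genes, 51 rose and 19 fell as deposited, and 74 rose and 10 fell after rescaling.

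At 2 d fewer genes passed the test than at 12 h or 7 d. The largest rises were in gene10040, from 11.6 ± 6.09 to 121 ± 104 FPKM, and Novel00129, from 0.525 ± 0.122 to 12.7 ± 10.8 FPKM (SD, n = 3). Their log2 fold changes were 3.06 (SE 0.66) and 2.89 (SE 0.72), with limma adjusted p of 0.0017 and 0.0048. The largest falls were in gene1870, from 57.3 ± 37.8 to 5.76 ± 1.89 FPKM, and gene7985, from 9.92 ± 6.73 to 0.407 ± 0.207 FPKM (SD, n = 3). Their log2 fold changes were -2.92 (SE 0.46) and -2.79 (SE 0.37), with limma adjusted p of 9.71e-05 and 1.68e-05. After rescaling the changes were 3.13, 3.25, -2.96 and -3.14 on the log2 scale. With voom (limma) on the recovered reads, an alternative chosen after seeing the data, Novel00129 no longer passed (log2 fold change 4.21, adjusted p = 0.088).

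The 2-d test called 1218 genes that rose and 1771 that fell (30.0%), around a median log2 fold change of -0.03. Which direction held more genes depended on the scaling: after rescaling 1920 rose and 1841 fell. The number of rises also depended on single libraries: without replicate 3 of the 2-d controls 667 genes rose and 1541 fell, and without replicate 3 of the 2-d atrazine cultures 783 rose and 1558 fell. In the top quartile of genes by mean FPKM, 321 rose and 745 fell as deposited, and 422 rose and 662 fell after rescaling. At 12 h, 569 of that quartile rose and 1136 fell as deposited, and 1085 rose and 480 fell after rescaling, so falls outnumbered rises at both times as deposited and at 2 d alone of these times after rescaling.

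**Figure D2:**
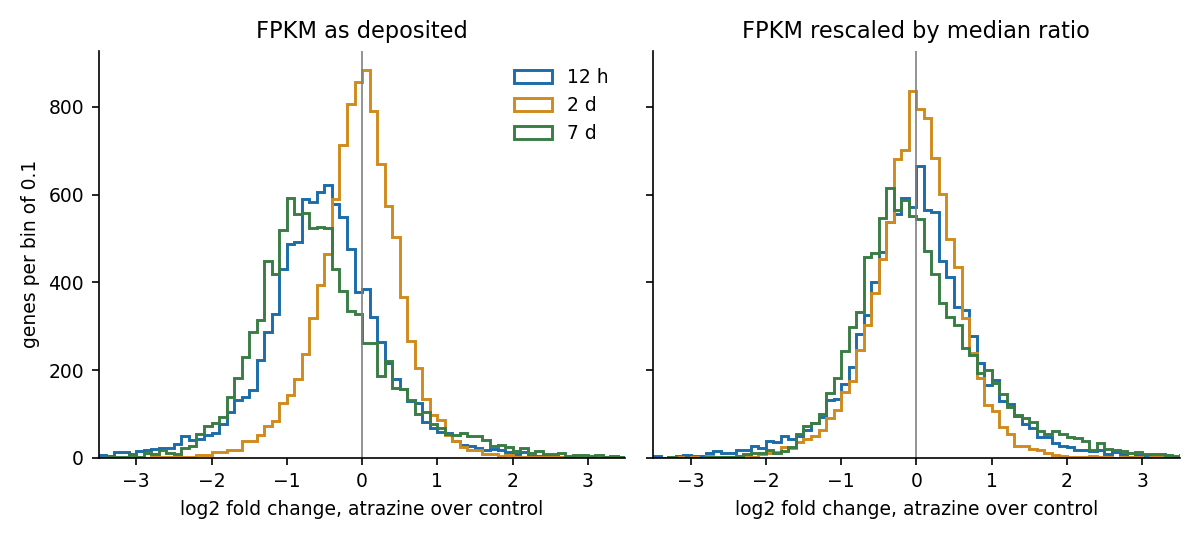
Histograms of the log2 fold change of atrazine over control for 9972 genes, in bins of 0.1, for FPKM as deposited (left) and rescaled by median ratio (right). As deposited the medians are -0.51 at 12 h, -0.03 at 2 d and -0.64 at 7 d, and after rescaling all lie near 0 by construction. In all 47 genes (left) and 58 genes (right) have a value beyond the axis limits of -3.5 and 3.5.

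At 7 d more genes passed the test than at 12 h, as deposited (7515 against 6562) and after rescaling (5737 against 5239). As deposited with 1 library left out in turn the counts overlapped, at 6796 to 7256 at 7 d and 5700 to 7073 at 12 h. With rescaling and 1 library left out, alternatives chosen after seeing the data, the order depended on which libraries were left out: each in turn gave 4890 to 5376 genes at 7 d and 4469 to 5337 at 12 h. Without replicate 3 of the 7-d atrazine cultures the 7-d count was 4890, against 5337 without replicate 3 of the 12-h controls and 5115 without replicate 2 of the 12-h atrazine cultures. The largest rises were in gene10040, from 7.33 ± 1.19 to 569 ± 38.7 FPKM, and gene1887, from 54.6 ± 9.95 to 1883 ± 287 FPKM (SD, n = 3). Their log2 fold changes were 6.10 (SE 0.66) and 5.09 (SE 0.54), with limma adjusted p of 3.37e-07 and 3.00e-07. The largest falls were in gene4181, from 36.3 ± 3.61 to 1.30 ± 0.0946 FPKM, and gene8386, from 70.7 ± 7.58 to 5.85 ± 1.19 FPKM (SD, n = 3). Their log2 fold changes were -4.02 (SE 0.23) and -3.40 (SE 0.19), with limma adjusted p of 2.50e-10 and 2.15e-10. After rescaling the changes were 6.57, 5.68, -3.30 and -2.75 on the log2 scale.

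In all, 1333 genes rose and 6182 fell at 7 d (75.4%), around a median log2 fold change of -0.64. After rescaling 2749 rose and 2988 fell. All 1333 genes that rose as deposited also rose after rescaling, 2988 of the 6182 that fell also fell, and 7 of them rose. Rescaling again raised the fold changes across genes (lower quartile from -1.09 to -0.51, upper quartile from -0.07 to 0.49), so the kept rises are no separate support. Among the 100 most abundant genes 39 rose and 33 fell as deposited, and 61 rose and 14 fell after rescaling.

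**Figure D3:**
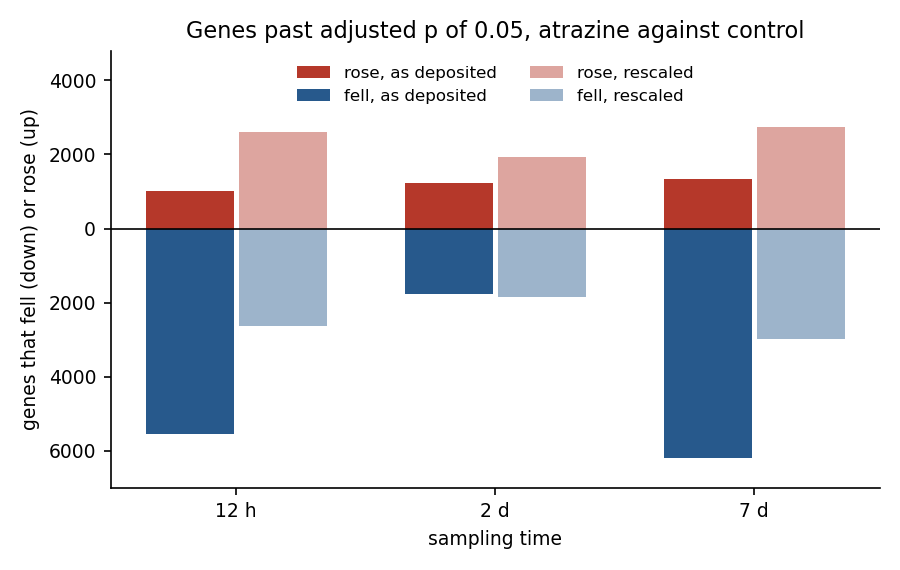
Bars give the number of genes past an adjusted p of 0.05 that rose (upward) or fell (downward) with atrazine at each time, for FPKM as deposited (dark) and rescaled by median ratio (pale). As deposited 5555 genes fell at 12 h and 6182 at 7 d, against 2629 and 2988 after rescaling.

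The effect of atrazine on single genes differed between times when the difference itself was tested. The limma test of the difference called 5622 genes between 2 d and 12 h. Of these, 4449 had the higher signed log2 fold change at 2 d and 1173 at 12 h. The same test called 3330 genes between 7 d and 12 h (1698 higher at 7 d and 1632 at 12 h). It called 6610 between 7 d and 2 d (1597 higher at 7 d and 5013 at 2 d). A higher signed value may be a weaker fall, as the median log2 fold changes were -0.51 at 12 h, -0.03 at 2 d and -0.64 at 7 d. After rescaling the splits were 2418 and 2274, 1894 and 1598, and 2754 and 2993. The IDs gene9921 and gene2447, which rose at 12 h, fell at 7 d, with log2 fold changes of -1.53 and -1.47 and limma adjusted p of 0.0013 and 0.00017; after rescaling these were -0.95 and -0.89, with adjusted p of 0.026 and 0.0063. For gene1093 and gene7272 the falls were smaller at 2 d, at -1.66 and -1.85, and at 7 d, at -1.86 and -1.75. The rise of gene10040 was larger at 7 d than at 2 d by 3.05 on the log2 scale (SE 0.93, limma adjusted p = 0.0076). At 12 h this ID ranged from 29.3 to 515 FPKM over the 3 controls.

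**Figure D4:**
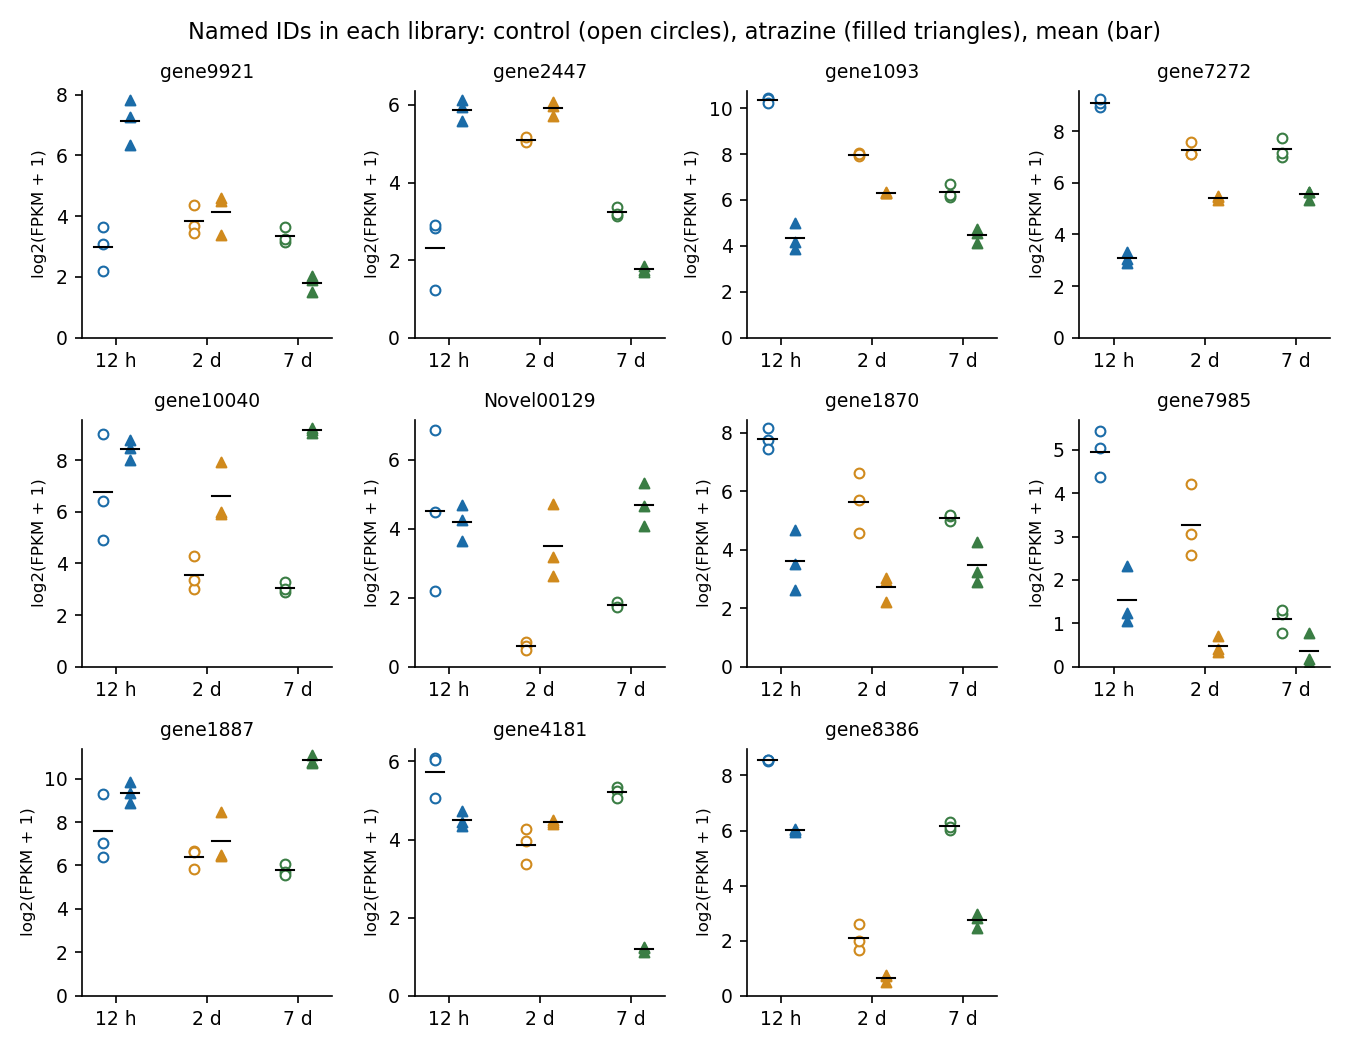
Each panel shows log2(FPKM + 1) of a named ID in every library by time, with open circles for controls, filled triangles for atrazine cultures and a bar at the mean of 3 replicates. The ID gene10040 separates the groups most at 7 d (7.33 against 569 FPKM on average), while its 12-h controls spread from 29.3 to 515 FPKM.

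Responses at 12 h and 7 d resembled each other across genes more than either resembled that at 2 d. The log2 fold changes at 12 h and 7 d correlated at a Pearson r of 0.47 (jackknife SE 0.08; Spearman 0.47), at 12 h and 2 d at 0.10 (SE 0.08; Spearman 0.03), and at 2 d and 7 d at -0.25 (SE 0.11; Spearman -0.29). These comparisons share no libraries, and genes are not independent replicates. After rescaling r was 0.49, 0.10 and -0.24. Rescaled effects also followed expression level, at a Spearman correlation of 0.25 at 12 h, -0.12 at 2 d and 0.33 at 7 d. How much of the correlations between times goes with that trend was not tested. In rescaled values 1473 genes rose and 1384 fell at both 12 h and 7 d, where independent lists of these sizes share 720 and 788. At both 12 h and 2 d 512 rose and 612 fell, against 503 and 485. Genes that fell at 2 d and rose at 7 d numbered 856, against 508 for independent lists, and those that rose at 2 d and fell at 7 d numbered 819, against 575. Across the 3 times 158 genes rose and 256 fell at every time after rescaling, where independent lists give 139 and 145. As deposited 34 rose and 555 fell at every time, where independent lists give 16.4 and 612, so for falls the excess turned with the scaling.

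**Figure D5:**
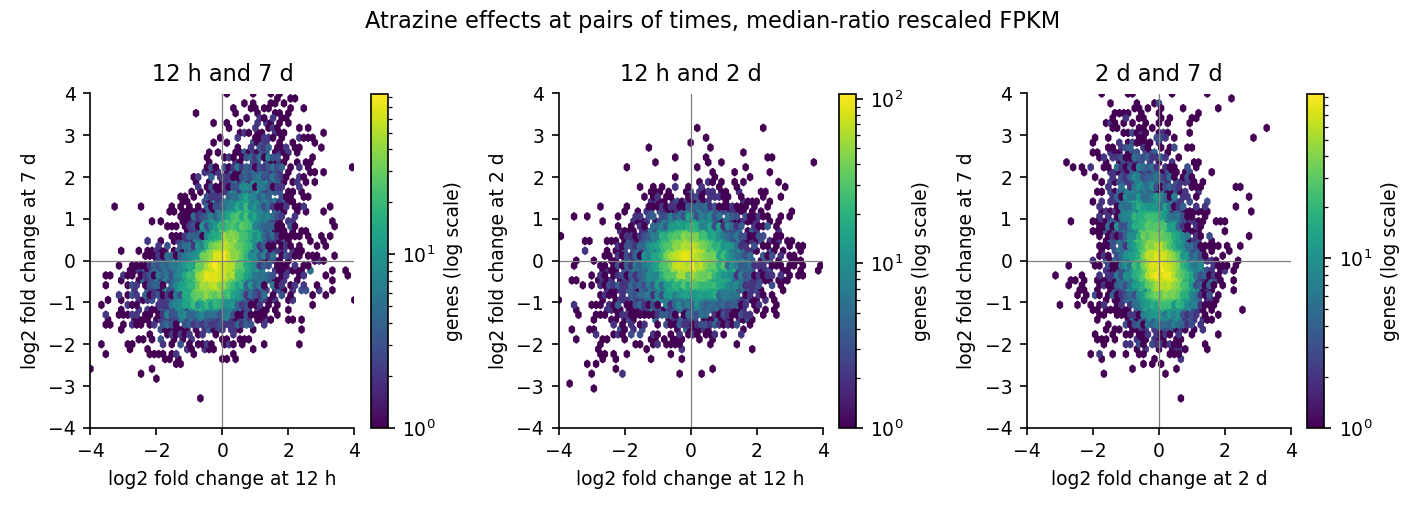
Hexagons count genes by their log2 fold change (atrazine over control, rescaled by median ratio) at 2 times, with a log colour scale. The cloud slopes upward for 12 h and 7 d (r = 0.49), is nearly round for 12 h and 2 d (0.10) and slopes downward for 2 d and 7 d (-0.24); 24 genes lie beyond the axis limits of -4 and 4.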

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

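The tests of the fall of most genes, of mixed or wrongly labelled material in a 12-h control, and of other splits of the libraries were chosen after those results were seen.

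The effect of atrazine differed between times for 5622 genes (2 d and 12 h), 3330 genes (7 d and 12 h) and 6610 genes (7 d and 2 d). Of 100 splits of the 12 libraries, 1, 6 and 1 gave as many genes, the real split included, and the highest other splits gave 5082, 5266 and 6575. The splits mix libraries of different times, so they carry the large change with time, a structure of the samples. For that reason this count neither excludes chance nor leaves it open for any of the 3 differences.

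Among the named IDs, each was flagged because its effect differed between times, and the largest difference is given as the later minus the earlier log2 fold change. Between 7 d and 12 h it was -5.70 for gene9921, -5.03 for gene2447, 4.26 for gene7272, 4.47 for gene10040, 2.54 for gene1870 and 2.67 for gene7985. For gene7985 the 7-d FPKM was low, at 1.16 in controls and 0.306 with atrazine. There log2(FPKM + 1) understates a fall, so the size of its difference depends on that scale. The value for gene10040 depends on the 12-h controls: it was 3.35 without replicate 3 and 5.40 without replicate 1. Between 2 d and 12 h the largest difference was 4.35 for gene1093 and 3.20 for Novel00129. The value for Novel00129 rests in part on replicate 3 of the 12-h controls, at 114 FPKM against 3.55 and 21.5 in the other 12-h controls: without it the difference was 2.04, and the 12-h log2 fold change went from -0.31 to 0.85. Between 7 d and 2 d the largest difference was 4.35 for gene1887, -4.59 for gene4181 and -1.97 for gene8386. The value for gene8386 depends on the scaling. As deposited its log2 fold changes were -3.40 at 7 d and -1.43 at 2 d, and after rescaling they lay closer, at -2.75 and -1.65. Its 2-d FPKM was low, at 3.41 in controls and 0.579 with atrazine.

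For atrazine against control, the 10 splits of 6 libraries are too few for a share under 0.05. The real split, 1 of the 10, gave 6562 genes at 12 h (highest other 618), 2989 at 2 d (highest other 0) and 7515 at 7 d (highest other 0). Between control groups the real split gave 7988 genes at 2 d and 7269 at 7 d against 12 h, each 1 of 10, with 0 in the highest other split. Every other split mixes libraries of both real groups, so the real difference enters the spread within groups and lowers the count. The low counts of the other splits therefore carry no evidence about chance.

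Most genes were lower in FPKM with atrazine at 12 h and 7 d. Without the 100 most abundant genes the median log2 fold change was -0.28 at 12 h and -0.51 at 7 d, against -0.51 and -0.64 with all genes. Most of the 7-d shift thus stayed without those genes. At 12 h the shift was smaller without them. The jackknife SE of 0.11 at 12 h belongs to the median over all genes, and no spread was computed for -0.28. How much of the 12-h shift goes with those genes therefore cannot be told. A depth difference, which FPKM already divides out, is argued against by log2 depth ratios of 0.034 and -0.0047. Reads spread evenly over genes in the controls would need 6.69 and 9.84 FPKM to make the whole gap between group medians. In the control library with the fewest such genes, 13.4% and 15.1% lay under that level, which argues against it. A smaller background behind part of the shift was not tested. A change of many transcripts relative to the rest also stays open, since FPKM gives no amount per cell. Atrazine as the biological source of such a change was not tested apart from this.

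Replicate 3 of the 12-h controls lay towards the treated libraries. Treated material mixed in would move rising and falling genes by a like share of the way, but the median share was 3.55% over 63 genes that rose over 4-fold (95% bootstrap interval -1.56 to 9.14) and 33.0% over 482 that fell (28.3 to 39.5). A treated library with a control label is argued against by its correlations, whose lowest with controls exceeded the highest with treated libraries by 0.059. Its deviation correlated across genes at 0.13 with the control change from 7 d to 2 d, which runs backwards in time, and at -0.05 once level and length classes were removed, a check chosen after the first value was seen, so whether it follows a change that controls show stays undecided.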

How the results depend on the processing

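Of 161 alternatives over 8 counts of genes, 152 gave a count within 1.5 times. That range is of totals and is blind to direction. At 12 h median-ratio rescaling and quantile normalization lay within it, with 2610 and 2791 rises against 1007 as deposited. Falls were 2629 and 2730 against 5555. An absolute log2 fold change of at least 1 gave 2676 genes at 12 h, 774 at 2 d, 3555 at 7 d, 3366 for 2 d against 12 h, 1965 for 7 d against 12 h, and 5118 and 3010 in controls at 2 d and 7 d, since it asks more of each gene. At 7 d, rescaling with 1 library left out, chosen after seeing the data, gave 4890 without replicate 3 of the atrazine cultures and 4912 without replicate 2 of the controls. The cause was not tested there. The 6 such settings gave 4890 to 5376 at 7 d and 4469 to 5337 at 12 h.

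Leaving out each replicate gave 5700 to 7073 genes at 12 h, 2124 to 2794 at 2 d and 6796 to 7256 at 7 d. Voom on recovered whole reads, chosen after seeing the data, called 6554, 2744 and 7631. With only the 6 libraries of a time the counts were 5513 at 12 h, 3260 at 2 d and 7985 at 7 d. For gene9921 at 12 h the limma adjusted p was then 5.29e-05, against 2.83e-08 in the joint fit. The joint fit shares an estimate of spread over groups of unlike spread. The median replicate SD on the log2 scale ran from 0.14 in 7-d controls to 0.25 in 12-h controls.

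The median log2 fold change moved with the scaling by construction. With median-ratio rescaling it was -0.0026 at 12 h and -0.076 at 7 d, with quantile normalization 0.028 and -0.085, and without the 100 most abundant genes -0.28, 0.052 (2 d) and -0.51. That removal, chosen after seeing the data, gave 1508 rises and 3997 falls at 12 h, 1705 and 1476 at 2 d, and 1354 and 1965 for 7 d against 12 h.

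Deviations of control and atrazine libraries with equal replicate numbers correlated at -0.02, 0.17 and 0.37 at 12 h, where unequal numbers gave -0.33 to 0.25. Equal numbers gave -0.25 to -0.11 at 2 d and -0.10 to 0.04 at 7 d. So the replicate numbers showed no pairing at 2 d and 7 d, and at 12 h it stays undecided. With the number as a block the counts were 6497, 2978 and 7474, for differences between times 5584, 3287 and 6576, and in controls 8006 and 7253. The correlations of effects between times kept their sign in all 15 alternatives each. Over 240 alternatives for named IDs, 239 kept direction and call, and 0 reversed; Novel00129 at 2 d had a log2 fold change of 4.21 and limma adjusted p = 0.088 with voom, the highest. The gene list tests and their alternatives were not run, because the IDs carry no names. At an FPKM of 1 about 24.3 reads stood behind a gene of median length, which limits low genes.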

Other observations

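Whether atrazine effects follow the change of control cultures between sampling times was tested after the first such correlations had been seen. The tests for level, length and single libraries were written before their results.

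Genes whose IDs carry a prefix other than gene, 177 of those tested, fell less often than others as deposited: 81 (45.8%) against 55.9% at 12 h, and 88 (49.7%) against 62.2% at 7 d (Fisher's exact test, adjusted p = 0.045 and 0.012 over 12 tests). After rescaling the shares were 24.9% against 26.4% and 22% against 30.1%, with adjusted p of 0.835 and 0.081. At 2 d 18.6% fell, against 17.7% of the others. Genes within a comparison are not independent.

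Genes with consecutive ID numbers had related atrazine effects: over 9356 pairs the rescaled log2 fold changes correlated at 0.14 at 12 h, 0.15 at 2 d and 0.17 at 7 d (permutation p = 0.0001 each, the smallest that 10000 permutations give). At a gap of 2 numbers the values were 0.04, 0.04 and 0.05, and at a gap of 10 they were -0.02, 0.01 and -0.0044.

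Atrazine effects at 2 d and 7 d correlated with the change of control cultures between the other times, in comparisons that share no libraries. In rescaled values the 7-d effect correlated at 0.40 (jackknife SE 0.07) with the control change from 12 h to 2 d, the 2-d effect at 0.36 (SE 0.04) with that from 12 h to 7 d, and the 12-h effect at 0.16 (SE 0.04) with that from 7 d to 2 d, which runs backwards in time. With the median of each level and length class removed, the values were 0.28, 0.34 and 0.020, which argues against such a trend as the whole of the 7-d and 2-d relations and goes with it for 12 h. Leaving out any of the 12 libraries left at least 0.37, 0.33 and 0.14, so no single library made them. No biological explanation was tested.

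Of the 3350 genes that rose in controls from 12 h to 2 d, 1577 rose and 539 fell with atrazine at 7 d, and of the 3675 that fell, 363 rose and 1732 fell (rescaled values), where 27.6% of all genes rose and 30.0% fell. The shares were 47.1% and 16.1% in the first set, and 9.88% and 47.1% in the second. Of the 2494 genes that rose in controls from 12 h to 7 d, 828 rose and 142 fell with atrazine at 2 d (33.2% and 5.69%), and of the 2771 that fell, 321 rose and 972 fell (11.6% and 35.1%), where 19.3% of all genes rose and 18.5% fell.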
